A study of Homo sapiens with 9 samples.

How the data were processed

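RNA of LNCaP cells was measured on 9 Affymetrix HG_U95Av2 arrays: 3 with solvent control, 3 with 300 nM DHT and 3 with 300 nM DHEA, each after 48 h. Per the labels there were 3 separate experiments with 1 array of each group, and the number in a label gives the experiment. The deposited values are intensity values per probe set made by the authors with dChip (model-based expression, version and settings not stated), on a linear scale. No raw scans were used here.

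As deposited, 2 columns (DHEA of experiments 1 and 3) did not correlate with the other 7 (median r = 0.0255 and 0.0224), though they did with each other. Their values stand in another order of probe sets than the ID column. The order was worked out from the arrays of experiment 2 alone, as 87 stretches of consecutive IDs that use each of 10566 probe sets once, plus shorter blocks. With it the median r with the other 7 arrays became 0.970 and 0.977, and a shift by 1 place gave 0.180 and 0.170. The deviations of these arrays from experiment 2 correlated with those of the control and DHT arrays of the same experiment at 0.887 and 0.774 and with those of the other experiment at 0.441 and 0.394. In all 11630 probe sets were placed, and 928 without a certain place were left out for these 2 arrays.

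The array medians as deposited range from 268 to 647, and against the control of the same experiment the log2 median was -0.62 for DHEA in experiment 1, -0.28 and -0.26 for DHT and DHEA in experiment 3 and 0.22 for DHEA in experiment 2. The plan, written before the values were seen, took the values as deposited. Because the arrays are not on a common level, this was changed after the medians were seen, and the arrays were quantile normalized, a step the plan held as an alternative. The values as deposited became an alternative instead, and they give many more calls (127, 42 and 1 in place of 7, 1 and 0), so the choice is the stricter of the 2 in number of calls. It is not the stricter in number of unadjusted p under 0.05: 1304 against 480 with DHT and 1006 against 488 with DHEA. Under the values as deposited the median probe set moves by -0.09 with DHT, -0.21 with DHEA and 0.12 between them.

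Of 12625 probe sets 67 are control sets (AFFX) and were left out. Values under a floor of 134 (the 20th percentile of all values) were set to it, then log2 was taken, and a probe set was kept if above the floor on at least 3 of 9 arrays: 10277 for DHT against control and 9492 where DHEA takes part. The platform table names 11506 probe sets, 10961 of them with 1 gene, and 1070 were not listed there and are called by their ID. A gene with several probe sets takes the one of highest mean, which gives 7064 genes. On each array 10017 to 10049 probe sets lie above the floor, a number nearly fixed by the normalization. With 3 arrays per group the median standard error of a log2 difference is 0.0991 for DHT and 0.0986 for DHEA.

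Groups were compared with limma 3.58.1 in R 4.3.3, with the experiment as a fixed block, eBayes with trend, Benjamini-Hochberg adjustment over probe sets and a threshold of adjusted p under 0.05, two-sided. The comparisons were DHT against control, DHEA against control, DHT against DHEA, and an F test for any difference. The fit leaves 4 residual degrees of freedom, 9.05 with the moderated part. That the numbers pair the arrays was checked before calls were compared: after the group means are taken out, arrays of the same experiment correlate at 0.720, 0.626 and 0.375 (DHT and control), 0.696, 0.694 and 0.408 (DHEA and control) and 0.826, 0.822 and 0.739 (DHT and DHEA). Other tables and the plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

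Gene lists (22) were written before the values were seen: androgen-induced, androgen-repressed, sterol synthesis, fatty acid synthesis, secretory pathway and unfolded protein, amino acid response, polyamine, cell cycle, steroid metabolism, estrogen-induced, insulin-like growth factor axis, neuroendocrine, luminal epithelial, hypoxia, heat shock, interferon response, immediate early, oxidative phosphorylation and ribosome biogenesis genes, and stromal, leukocyte and endothelial, and basal epithelial markers. They were tested with camera in limma at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, with an estimated correlation and fry as alternatives. Members were also adjusted over the list alone. Means and tests of a list take the genes measured on all 9 arrays, while for DHT against control the counts of members, and means given by experiment, also take genes not placed on the reordered arrays (51 against 46 for cell cycle genes, 44 against 42 for androgen-induced genes and up to 4 more in 12 other lists).

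The genes named were set by rule beforehand: the 12 largest rises and falls among those that pass with the same sign in 3 experiments, or, where fewer than 5 pass in a direction, the 5 of smallest p there as not passing. A fixed set of genes is always given where analysed here, up to 4 members of smallest p per list may be named, and list members that passed over the list alone are given as examples. S100P and AGR2 with DHEA were looked up after their values with DHT were seen. No second probe set of a named gene passed in either direction. Some lay on the other side of 0 from the one used, as with DHT for CDH1 (0.05) and SAT1 (-0.11).

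The responses to DHT and DHEA share their control arrays, so the correlation and the overlap that these alone give were simulated 100 times, and DHT of one experiment was also set against DHEA of another. In data simulated with the spread of the fit, 43, 48, 50 and 50 of 50 changes of 1.5, 2, 3 and 4-fold were recovered for DHT against control. All were planted at once, and with so many calls the adjustment lets larger p-values pass than in the real data, where 7 probe sets passed. These shares thus do not carry over: in the real data H2AX did not pass at a log2 difference of 1.48. In the simulated data 24 of 215 calls were false, as were 8 of 200 for DHEA against control and 13 of 208 between the steroids, so the 5% aimed at is exceeded in 2 of 3 comparisons. A simulated list was called and 0 of the other 21 lists were, in noise that is independent between genes. Genes of the real lists move together (estimated correlation 0.603 for cell cycle genes), so this run does not check the list test on them.

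RNA quality was read from the 3'/5' ratios of the GAPDH and actin control probe sets, placed for the 2 reordered arrays by the order of these sets on the array as recalled, which no file used here gives. Alternatives planned beforehand changed the block, floor, pseudocount, filter, normalization, variance model, arrays in the fit, threshold and list test, and left out each experiment and each array in turn. Added after the values were seen were fits without the 2 reordered arrays, without the 2 arrays of high 3'/5' ratio, with the order as deposited and with the actin ratio as a covariate. The use of quantile normalization as the main setting was also chosen then. For other splits of the samples the 6 arrays of a comparison were parted 3 against 3 in all 10 ways, and for the F test the labels were exchanged within experiments in 36 ways.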

Results

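LNCaP cells, an androgen-responsive human prostate cancer line, were kept for 48 h with 300 nM dihydrotestosterone (DHT), 300 nM dehydroepiandrosterone (DHEA) or solvent alone. DHT is a potent androgen, and DHEA is an adrenal steroid that cells can turn into androgens. The 2 steroids differ in 3 places: DHEA has a hydroxyl on ring A, a double bond in ring B and a ketone on ring D, and DHT has a ketone on ring A, a saturated ring B and a hydroxyl on ring D. There were 3 separate experiments with 1 array of each group, so n = 3 arrays per group. The solvent of the control was DMSO in experiment 1 and ethanol in experiments 2 and 3. Values are differences in log2 intensity, paired within experiments, with the standard error after ±. Of the genes set beforehand to be given in every comparison, FOLH1 and HSD3B1 were not analysed here.

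With DHT, 4 named genes rose and 2 fell (limma, experiment as block, adjusted p under 0.05), each in the same direction in 3 of 3 experiments. The largest rise was in S100P, a calcium-binding protein of the S100 family, by 2.49 ± 0.29 or 5.63-fold (limma adjusted p = 0.0343). AGR2, a disulfide isomerase of the endoplasmic reticulum, rose by 1.61 ± 0.21, and DBI, which binds acyl-CoA esters, by 1.34 ± 0.18 (limma adjusted p = 0.046 each). MCCC2, a subunit of the mitochondrial enzyme that breaks down leucine, rose by 1.44 ± 0.16 (limma adjusted p = 0.0281). NTS, the precursor of the peptide neurotensin, fell by 2.13 ± 0.21, or 4.38-fold (limma adjusted p = 0.0163), and DDC, aromatic amino acid decarboxylase, fell by 0.82 ± 0.11 (limma adjusted p = 0.046). A probe set that the platform table does not name, 36658_at, rose by 1.46 ± 0.10 (limma adjusted p = 0.00196).

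Below the threshold, the genes of smallest p on the higher side were ALDOA (0.48 ± 0.07), CENPX (0.73 ± 0.11), H2AX (1.48 ± 0.24), POLR1F (0.64 ± 0.11) and FASN (0.48 ± 0.08). On the lower side they were PRKD1 (-0.65 ± 0.09), VPS13B (-0.61 ± 0.09), PLCB4 (-0.78 ± 0.11), ITPRID2 (-0.70 ± 0.10) and LRBA (-0.66 ± 0.10). The classic androgen targets, which did not pass over all probe sets either, stood at 0.62 ± 0.17 for KLK3 (prostate-specific antigen), 1.46 ± 0.41 for KLK2, 0.86 ± 0.28 for TMPRSS2 and 1.11 ± 0.35 for FKBP5. Other KLK3 probe sets stood higher than the one used, at 0.66 to 1.39. KLK2 was 2.16 higher in experiment 1, 0.00 in experiment 2 and 2.21 in experiment 3, and TMPRSS2 was 1.09, 0.00 and 1.48. UGT2B15, which conjugates androgens, stood at -0.54 ± 0.18, and HSD17B4, which oxidizes 17-beta-hydroxysteroids, at 0.38 ± 0.12. Near 0 were MKI67 (0.07 ± 0.09), ESR2 (-0.08 ± 0.10), STS (0.04 ± 0.08), IGFBP3 (-0.04 ± 0.09), IGF1R (0.01 ± 0.09) and SRD5A1 (-0.01 ± 0.10).

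Cell cycle genes formed the largest group: of 51 measured, 50 were higher with DHT and 1 lower (mean 0.72; camera in limma, adjusted p = 2.4e-28; 0.331 with an estimated correlation in place of the preset one), and 41 rose adjusted over the list alone, among them CKS2 (1.55 ± 0.30), CDC6 (1.29 ± 0.26), RRM2 (1.11 ± 0.23) and MCM6 (0.92 ± 0.17). Over the 51 genes the mean was 0.99 in experiment 1, 0.03 in experiment 2 and 1.10 in experiment 3, while the list mean and its test take the 46 genes measured on all 9 arrays. Among 44 androgen-induced genes 33 were higher (mean 0.37; limma adjusted p = 3.58e-09; 0.433 with an estimated correlation), and adjusted over the list alone 18 rose and 1 fell. Those that rose include MAF (1.06 ± 0.19), TNFAIP8 (1.19 ± 0.24) and UAP1 (0.80 ± 0.15), with KLK3, KLK2, TMPRSS2 and FKBP5. The 1 that fell is PTK2B, a kinase (-0.29 ± 0.08). Of 13 androgen-repressed genes 9 were lower (mean -0.41; limma adjusted p = 2.17e-05; 0.331 with an estimated correlation), and 8 fell adjusted over the list alone, with BCHE (-0.77 ± 0.13), CCN3 (-0.37 ± 0.07), ACKR3 (-0.81 ± 0.18), UGT2B17 (-1.08 ± 0.32) and UGT2B15.

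Genes of lipid synthesis were also higher. Of 20 sterol synthesis genes 18 were higher (mean 0.40; limma adjusted p = 1.87e-09; 0.314 with an estimated correlation), and 9 rose adjusted over the list alone, with FDPS (0.96 ± 0.22), INSIG1 (1.16 ± 0.27), MSMO1 (0.91 ± 0.22) and DHCR7 (0.36 ± 0.08). Of 14 fatty acid synthesis genes 13 were higher (mean 0.32; limma adjusted p = 1.81e-07; 0.314 with an estimated correlation), and DBI, FASN, FADS2 (0.69 ± 0.12) and ELOVL5 (0.46 ± 0.09) rose adjusted over the list alone. Of 11 polyamine genes 8 were higher (mean 0.24; limma adjusted p = 0.00059; 0.331 with an estimated correlation), and SMS (0.78 ± 0.18), ARG2 (0.43 ± 0.12) and SAT1 (0.35 ± 0.10) rose adjusted over the list alone.

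Differences were also called in 4 more lists. Of 26 amino acid response genes 19 were lower (mean -0.15; limma adjusted p = 0.00219; 0.496 with an estimated correlation), led by CBS (-0.41 ± 0.10) and ASNS (-0.44 ± 0.12), and none passed adjusted over the list alone. Of 12 neuroendocrine genes 7 were lower (mean -0.30; limma adjusted p = 0.0352; 0.496 with an estimated correlation), with a median of -0.08 and only NTS and DDC passing. Of 17 ribosome biogenesis genes 16 were higher (mean 0.12; limma adjusted p = 0.00401; 0.433 with an estimated correlation). Of 25 hypoxia genes 18 were higher (mean 0.12; limma adjusted p = 0.00881; 0.601 with an estimated correlation), and only ALDOA, a glycolytic enzyme, rose adjusted over the list alone. In experiment 2 these 2 lists stood on the other side of 0, at -0.04 and -0.06.

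The other 12 lists were not called (limma adjusted p of 0.188 or above). Their means were -0.10 for immediate early, 0.03 for oxidative phosphorylation, -0.08 for estrogen-induced, -0.04 for interferon response, -0.07 for luminal epithelial, 0.01 for heat shock, 0.02 for insulin-like growth factor axis, -0.02 for secretory pathway and unfolded protein and -0.03 for steroid metabolism genes. Markers of other cell types stood at -0.05 (stromal), 0.01 (leukocyte and endothelial) and -0.03 (basal epithelial). In these lists XBP1, CDH1 and GATA2 fell adjusted over the list alone, by 0.70 ± 0.15, 0.45 ± 0.09 and 0.34 ± 0.09. A second probe set of CDH1 stood at 0.05 ± 0.10, and others of GATA2 at -0.71 ± 0.15, -0.06 ± 0.09 and -0.23 ± 0.08.

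**Figure D1:**
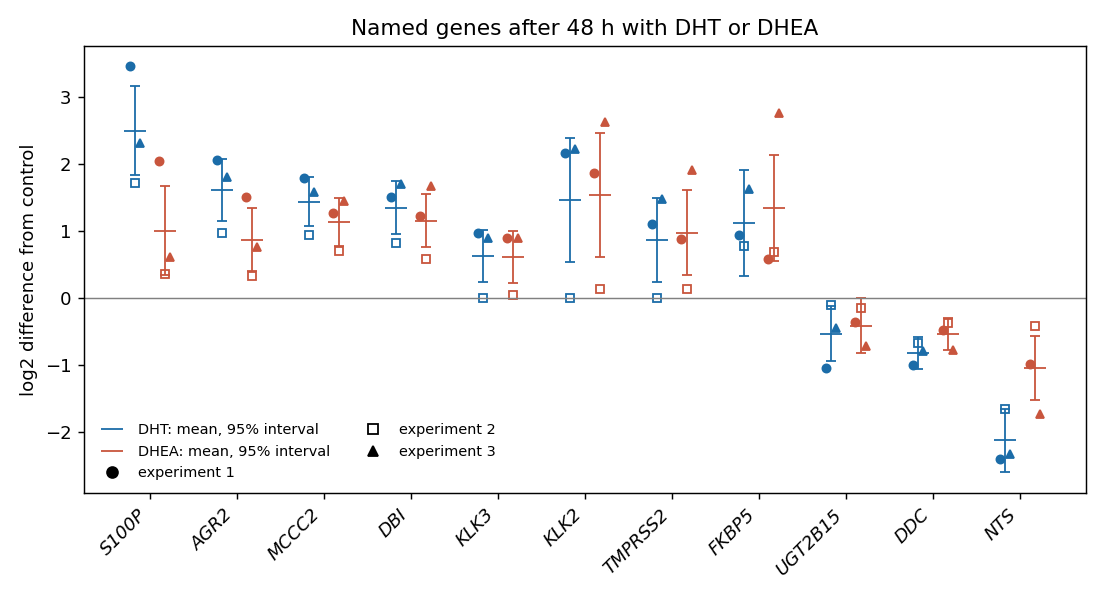
Log2 difference from the control of the same experiment for 11 named genes with DHT and DHEA. Bars give the mean and its 95% interval from the limma fit (n = 3 experiments), and symbols give the single experiments.

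In all, 7 of 10277 probe sets passed with DHT, 5 up and 2 down, and 1304 had an unadjusted p under 0.05 where chance alone gives 514. That excess depends on the settings: 480 of 10406 had such a p with the values as deposited, and 398 of 10277 without the experiment block. The counts move with the level between arrays and with single arrays: 7 probe sets passed after quantile normalization and 127 with the values as deposited, where the median probe set stood at -0.09, and 475 passed when only the control array of experiment 2 was left out. The arrays also differ in RNA quality, with a 3'/5' ratio of GAPDH of 2.65 in the control of experiment 3 against 1.39 with DHT. Without the experiment block, or on the 6 arrays of these groups alone, 0 probe sets passed. Leaving out the 2 DHEA arrays whose values had to be put back in order gives the same fit here as the 6 arrays alone, so it is no further check. Other splits of the same 6 arrays called up to 9 lists, against 10 for the true groups, and 0 probe sets, and those that part all 3 pairs also up to 9 lists.

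With DHEA no named gene passed. The genes of smallest p on the higher side were MCCC2 (1.13 ± 0.16), DBI (1.15 ± 0.18), MAF, a transcription factor (1.14 ± 0.19), FADS2, a fatty acid desaturase (0.76 ± 0.12), and PPIB, a cyclophilin of the secretory pathway (0.39 ± 0.06), each higher in 3 of 3 experiments (limma adjusted p = 0.18). On the lower side they were SCN9A (-0.48 ± 0.07), VPS13B (-0.53 ± 0.08), PLCB4 (-0.60 ± 0.11), ITPRID2 (-0.54 ± 0.10) and GALNT3 (-0.70 ± 0.13), each lower in 3 of 3 experiments (limma adjusted p = 0.18). The 1 probe set that rose was 36658_at, by 1.27 ± 0.10 (limma adjusted p = 0.00585), the same unnamed one that rose with DHT.

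The androgen targets stood at 0.61 ± 0.17 for KLK3, 1.54 ± 0.41 for KLK2, 0.97 ± 0.28 for TMPRSS2 and 1.34 ± 0.35 for FKBP5, with KLK2 at 1.86, 0.14 and 2.62 in experiments 1, 2 and 3. Here too the other KLK3 probe sets stood higher, at 0.73 to 1.40. UGT2B15 was at -0.42 ± 0.18 and HSD17B4 at 0.33 ± 0.12. The others set beforehand were IGF1R (0.13 ± 0.09), STS (0.09 ± 0.07), ESR2 (-0.07 ± 0.10), SRD5A1 (0.05 ± 0.10), IGFBP3 (0.03 ± 0.09) and MKI67 (0.01 ± 0.09).

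By groups, 33 of 42 androgen-induced genes were higher with DHEA (mean 0.43; camera in limma, adjusted p = 1.27e-14; 0.383 with an estimated correlation). Adjusted over the list alone 16 rose and 0 fell, among them TNFAIP8 (1.44 ± 0.24), CAMKK2 (0.67 ± 0.13), SMS (0.79 ± 0.18), MAF and DBI. Of 13 androgen-repressed genes 11 were lower (mean -0.33; limma adjusted p = 3.1e-05; 0.383 with an estimated correlation), and 5 fell adjusted over the list alone, with DDC (-0.55 ± 0.11), BCHE (-0.63 ± 0.12), CCN3 (-0.31 ± 0.07) and ACKR3 (-0.79 ± 0.18). Of 46 cell cycle genes 43 were higher (mean 0.53; limma adjusted p = 1.53e-18; 0.387 with an estimated correlation), and CDC6 (1.37 ± 0.26), MCM6 (0.81 ± 0.17) and CKS2 (1.20 ± 0.30) rose adjusted over the list alone. By experiment the mean of this list was 0.76, 0.07 and 0.78. The sterol list had 17 of 20 genes higher (mean 0.35; limma adjusted p = 1.76e-08; 0.383 with an estimated correlation), and 8 rose adjusted over the list alone, with MSMO1 (0.89 ± 0.22), INSIG1 (1.06 ± 0.27) and IDI1 (0.66 ± 0.17). The fatty acid list had 11 of 13 higher (mean 0.25; limma adjusted p = 2.19e-05; 0.383 with an estimated correlation), and DBI, FADS2, ELOVL5 (0.42 ± 0.09) and FASN (0.32 ± 0.08) rose adjusted over the list alone.

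Of 10 polyamine genes 7 were higher (mean 0.22; limma adjusted p = 0.00437; 0.383 with an estimated correlation), and SMS and ODC1 (0.59 ± 0.17), the enzyme that starts polyamine synthesis, rose adjusted over the list alone. Of 11 neuroendocrine genes 9 were lower (mean -0.21; limma adjusted p = 0.0205; 0.433 with an estimated correlation), and NTS (-1.05 ± 0.21) and DDC fell adjusted over the list alone. The ribosome biogenesis list had 12 of 15 higher (mean 0.10; limma adjusted p = 0.0151; 0.433 with an estimated correlation). The hypoxia list had 16 of 24 higher (mean 0.09; limma adjusted p = 0.0264; 0.583 with an estimated correlation), with ALDOA (0.38 ± 0.07) rising adjusted over the list alone.

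The remaining 13 lists were not called with DHEA (limma adjusted p of 0.0686 or above). Their means were -0.09 for amino acid response, -0.10 for immediate early, 0.07 for insulin-like growth factor axis, 0.05 for secretory pathway and unfolded protein, 0.04 for heat shock, -0.05 for interferon response, -0.08 for estrogen-induced, -0.05 for luminal epithelial, 0.00 for oxidative phosphorylation and -0.04 for steroid metabolism genes. Stromal, basal epithelial, and leukocyte and endothelial markers stood at -0.05, -0.04 and -0.01. GATA2 (-0.39 ± 0.09) fell and NDUFV1 (0.36 ± 0.07) rose adjusted over the list alone.

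**Figure D2:**
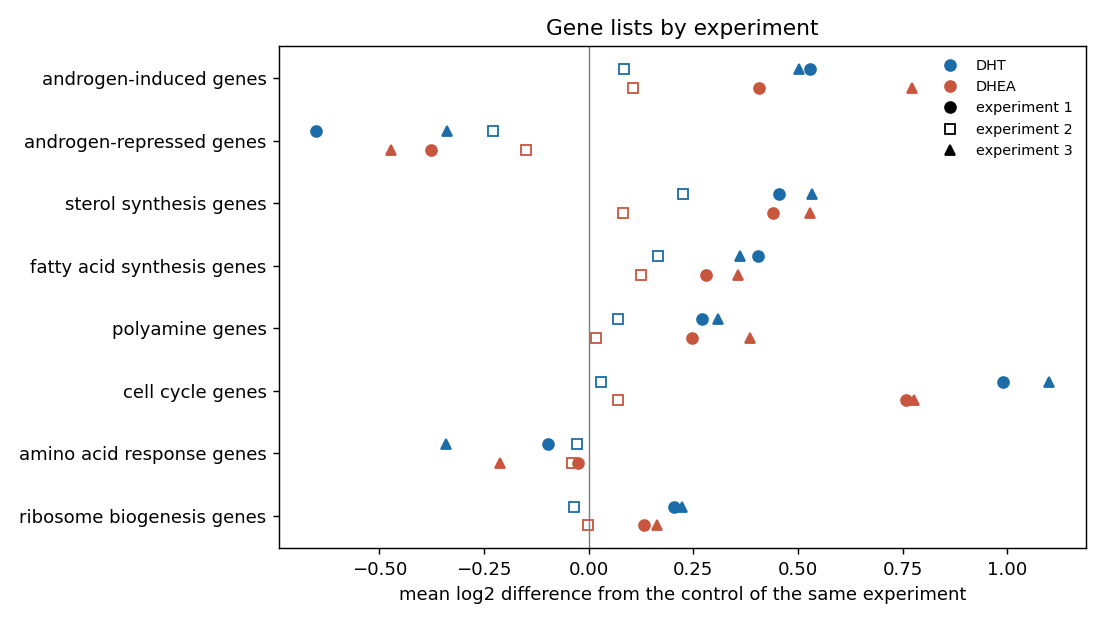
Mean log2 difference from the control of the same experiment over the genes of 8 lists, for DHT and DHEA. Each symbol is 1 experiment (1 treated array minus 1 control array).

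Over all, 1 of 9492 probe sets passed with DHEA, and 1006 had an unadjusted p under 0.05 where chance gives 475. Such a p was found for 488 of 9609 with the values as deposited, and for 245 of 9492 without the experiment block. With the values as deposited 42 passed, at a median of -0.21, without the control array of experiment 2 284 passed, and 0 passed without the 2 DHEA arrays whose values had to be put back in order, or without the experiment block. The DHEA array of experiment 1 had the highest 3'/5' ratio of GAPDH, 3.83. Other splits of the 6 arrays called up to 13 lists, and those that part all 3 pairs up to 11, against 9 for the true groups.

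No gene passed between DHT and DHEA at the same dose and time. The 2 largest differences were in genes that passed with DHT: S100P was higher with DHT than with DHEA by 1.49 ± 0.29 (95% interval 0.83 to 2.16) and NTS lower by 1.08 ± 0.21 (95% interval of the difference -1.56 to -0.61), each in 3 of 3 experiments (limma adjusted p = 1). AGR2 was 0.74 ± 0.21 higher with DHT (0.28 to 1.21). The others of smallest p on the higher side were SCN9A (0.27 ± 0.07), SPON1 (0.26 ± 0.09) and DHRS7 (0.22 ± 0.07), and on the lower side FAM110B (-0.28 ± 0.09), MARCHF2 (-0.27 ± 0.09), NAP1L1 (-0.24 ± 0.08) and PIEZO1 (-0.26 ± 0.09). A fit on the 6 arrays of these groups alone called S100P, at 1.49 ± 0.09 (limma adjusted p = 0.00541).

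For the androgen targets the differences lay near 0 with wide intervals: KLK3 0.01 (-0.38 to 0.40), KLK2 -0.08 (-1.0 to 0.85), TMPRSS2 -0.12 (-0.74 to 0.51) and FKBP5 -0.22 (-1.01 to 0.56). UGT2B15 stood at -0.12 ± 0.18, HSD17B4 at 0.05 ± 0.12, IGF1R at -0.12 ± 0.09, IGFBP3 at -0.07 ± 0.09, SRD5A1 at -0.06 ± 0.10, STS at -0.05 ± 0.07, MKI67 at 0.05 ± 0.09 and ESR2 at -0.01 ± 0.10. The median probe set has a 95% interval of ± 0.22, and for 9451 of 9492 probe sets (99.6%) the interval lies within a 2-fold difference. Most probe sets moved little against control (SD of the log2 fold changes 0.218 with DHT and 0.194 with DHEA), so this share does not show that the steroids act alike.

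As groups, 44 of 46 cell cycle genes were higher with DHT than with DHEA (mean 0.18; camera in limma, adjusted p = 1.56e-08; 0.839 with an estimated correlation), with RFC3 at 0.25 ± 0.10, KIF11 at 0.33 ± 0.20 and CENPE at 0.20 ± 0.12. By experiment their mean was 0.25, -0.05 and 0.35. Of 30 secretory pathway and unfolded protein genes 24 were lower (mean -0.07; limma adjusted p = 0.00113; 0.839 with an estimated correlation), with HSPA5 at -0.21 ± 0.08 and DNAJB9 at -0.29 ± 0.15. By experiment the mean of this list was -0.04, -0.004 and -0.18, and a fit without the 2 reordered arrays, which leaves 1 DHEA array, gave 0.012. Of 25 amino acid response genes 17 were lower (mean -0.06; limma adjusted p = 0.0408; 0.839 with an estimated correlation), with CBS at -0.19 ± 0.10 and ASNS at -0.17 ± 0.12, and in experiment 2 the mean was 0.01. In none of these lists did a gene pass adjusted over the list alone, and in the neuroendocrine list only NTS did.

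The other 19 lists were not called between the steroids (limma adjusted p of 0.0522 or above). Androgen-induced genes had a mean of -0.06 (0.05 with the values as deposited, where the median probe set stood at 0.12) and androgen-repressed genes of -0.07. The metabolic lists stood at 0.07 (fatty acid synthesis), 0.05 (sterol synthesis), 0.02 (polyamine), 0.03 (oxidative phosphorylation), 0.02 (hypoxia) and 0.00 (steroid metabolism). Means were -0.05 for insulin-like growth factor axis, -0.03 for heat shock, -0.09 for neuroendocrine, 0.02 for ribosome biogenesis, -0.02 for luminal epithelial, 0.01 for interferon response, 0.00 for immediate early and -0.01 for estrogen-induced genes. Leukocyte and endothelial, basal and stromal markers had means of 0.01, 0.01 and 0.00. Only 105 of 9492 probe sets had an unadjusted p under 0.05 where chance gives 475. On the 6 arrays of these groups alone 246 did, also under chance. So few small p-values mean that the test was too cautious here. Its spread also takes in the control arrays, but the fit without them stayed under chance too, and the cause was not tested. The lack of calls thus does not show that the steroids act alike. Other splits of the 6 arrays that part all 3 pairs called 0 probe sets and up to 7 lists (2 and 9 over all splits), against 0 and 3 for the true groups.

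The test for any difference among the 3 groups called 1 of 9492 probe sets, 36658_at, which rose with either steroid (limma F test, adjusted p = 0.00317). In all 889 probe sets had an unadjusted p under 0.05. With the values as deposited 99 passed, and 0 passed without the block, with no filter, without the 2 reordered arrays, without the 2 arrays of high 3'/5' ratio, or without experiment 1 or 3. Of 36 labellings within experiments 4, the true one among them, called as many, which is not under the share of 0.05 set beforehand. By that rule chance is not excluded. None of the 32 labellings that move a control called any, a count that was not planned.

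The responses to DHT and DHEA ran together over the genes. Of the probe sets with an unadjusted p under 0.05, 347 were higher with both steroids and 336 lower with both, where sets of the same sizes in data simulated with shared controls and no change shared 162 (at most 189) and 181 (at most 204) on average. None was higher with one and lower with the other, where the simulation gave 6.63 and 8.18. The log2 fold changes correlated at r = 0.893 (Spearman 0.804), where the shared control arrays alone gave r = 0.497 in simulation (highest of 100 runs 0.531). Equal spread on all arrays was assumed there, which fixes this r in advance, and controls that vary more would raise it. After group means were taken out, DHT and DHEA arrays of an experiment correlated at 0.739 to 0.826, and either with its control at 0.375 to 0.720. The simulated r and overlaps may thus be too low a mark. DHT in one experiment against DHEA in another, which share no array, gave r from 0.0826 to 0.497 (mean 0.267). Within single experiments, r was 0.807, 0.670 and 0.857. MCCC2 and DBI lie near the line of equal change (1.44 against 1.13, and 1.34 against 1.15), and S100P lies off it (2.49 with DHT, 1.00 with DHEA), as does NTS (-2.13 and -1.05). Without the 2 reordered DHEA arrays r was 0.711, and the correlations run across genes, which are not independent replicates.

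**Figure D3:**
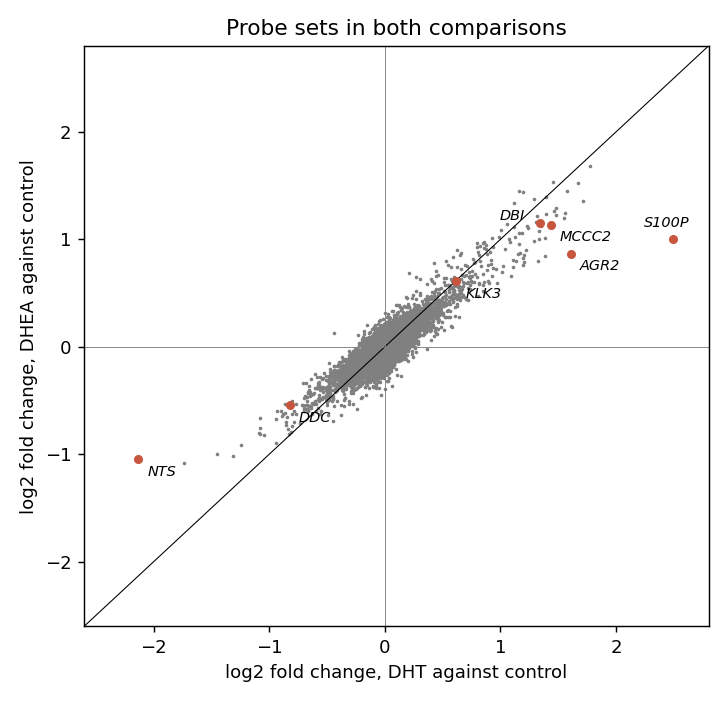
Log2 fold change with DHEA against that with DHT for 9492 probe sets, with 7 named genes marked. The diagonal is the line of equal change, and both axes use the same 3 control arrays.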

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

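Of the tests in this part only that of the level of cell cycle genes in the control of experiment 2 was set before its value was seen, and all others were chosen after the results. Here the value after ± is a standard error over the genes of a list on single arrays, or, for the shares, from resampling genes. Genes of a list move together (estimated correlation 0.603 for cell cycle genes). These errors thus do not measure the spread between cultures and are likely too small.

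The 3'/5' ratio of GAPDH, read from control probe sets that no comparison uses, was 3.83 in the DHEA array of experiment 1, above the highest control array (2.65). The ratio of actin was 3.48 there, below the 3.88 of that control. For this array the control probe sets were placed by an order that was recalled and is in no file used here, so the ratios hold only if it is right.

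Cell cycle genes were higher with DHT in experiments 1 and 3 (means 0.99 and 1.10) and not in experiment 2 (0.03). Smaller differences over all genes of experiment 2 are one technical candidate, but the share of experiment 2 in the other 2 was larger for sterol synthesis than for cell cycle genes by 0.426 ± 0.196. RNA quality is another, yet in experiment 1, where the control and DHT arrays have GAPDH ratios of 1.86 and 1.92, the mean was 0.990 ± 0.0889, and solvent one more, yet experiment 3 shared ethanol with experiment 2 and its mean was 1.10 ± 0.108. A biological candidate, control cells of experiment 2 already high in these genes, was tested too: that control lay 0.0887 ± 0.0441 above the mean of the other 2, which on these single arrays speaks against it. The cause stays open, and cells of experiment 2 that did not enter the cycle with either steroid may be a candidate not tested here.

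Androgen-induced genes differed little between DHT and control in experiment 2 (mean 0.08, against 0.53 and 0.50). There the control array itself lay high: 0.460 ± 0.103 above the mean of the other 2 controls, with KLK2 at 12.34 against 10.38 and 10.27. Residual androgen in that culture may be a biological candidate, and a treated sample labelled as control a technical one. For the latter, of 89 probe sets over 2-fold apart in the same direction in experiments 1 and 3, 56.2% kept that direction in experiment 2, within the 60% set for a wrong label, but 41 of 78 higher ones and 9 of 11 lower ones did (81.8%, past the 75% set against it), and 60.6% did without cell cycle genes. NTS was still 1.66 lower and S100P 1.72 higher with DHT in experiment 2, but both were picked for the same sign in 3 experiments, so they cannot weigh against a wrong label. The sterol synthesis genes were 0.22 ± 0.08 higher with DHT there. With DHEA of experiment 2 they were 0.08 higher, S100P stood at 10.66 against 10.31 in the control, and NTS at 10.07 against 10.49. These are single arrays, so a wrong label, for a DHT or a DHEA sample, is neither shown nor excluded.

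The DHEA arrays of experiments 1 and 3 did not correlate with the other 7 as deposited. Values set beside the IDs in another order would leave the arrays like their own experiment once put back: the lower of the 2 correlations with the own experiment was 0.774, against at most 0.441 with the other. A failed array or another kind of sample would stay apart, and the lower of the 2 median correlations after the change was 0.9698. A change of order is thus likely the cause, though the order was worked out from the same values.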

How the results depend on the processing

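Settings chosen only after the results were seen are the reordered arrays left out, the arrays of high 3'/5' ratio left out, the order of values as deposited and the actin ratio as a covariate, and quantile normalization was made the main setting then.

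Counts are given as DHT against control, DHEA against control, DHT against DHEA and the F test, which are 7, 1, 0 and 1 in the report, and only those that moved are named. Without the replicate block 0 passed in every comparison, and with a random block 3 passed with DHT and 2 in the F test. A floor at the 10th percentile gave 5 with DHT and 3 in the F test, and at the 40th 11 with DHT and 5 in the F test. A pseudocount gave 4 with DHT, no filter 0 with DHT, 0 in the F test and 1 with DHEA that is another probe set than in the report, and only the probe sets above the median level 19 and 4, with fewer probe sets tested. The values as deposited gave 127, 42, 1 and 99, and median scaling 3 with DHT. Without the trend 4 passed with DHT, with a robust fit 14, at a threshold of 0.10 26 (and 3 in the F test), and on the 6 arrays alone 0 with DHT and 1 (S100P) between the steroids. Without the reordered arrays, without the arrays of high 3'/5' ratio, and with the order as deposited, 0 passed in every comparison. For DHT against control, leaving out the reordered arrays gives the same fit as the 6 arrays alone. With the actin ratio as a covariate 3 passed with DHT and 3 with DHEA.

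Leaving out each experiment or array in turn gave from 0 to 475 with DHT, 0 to 284 with DHEA and 0 to 287 in the F test, the highest each time without the control of experiment 2. Where a group was left with 1 array, that array is assumed to vary like the others.

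The lists called (10 with DHT, 9 with DHEA, 3 between the steroids) were 0 in each with an estimated correlation and 0 with fry. Without the reordered arrays 5 were called with DHEA and 6 between the steroids, and with the values as deposited 5 between the steroids. Leaving out each experiment gave 5 to 11 with DHEA and 3 to 5 between the steroids. Without the reordered arrays DHEA keeps 1 array, and the fit then gives 0.12 for androgen-induced and 0.012 for secretory pathway and unfolded protein genes between the steroids, against means below 0 in the report. These come from the block model: within experiment 2, the only pair left, the means are -0.03 and -0.004. Over all comparisons the camera direction of 7 more lists, called in neither fit, changed too.

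The correlation of the 2 responses (0.893) was 0.711 without the reordered arrays, 0.721 without the arrays of high 3'/5' ratio, 0.104 with the order as deposited, and 0.832 to 0.897 leaving out an experiment.

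Among the named genes no called direction changed. NTS kept its call in 14 of 25 settings (-2.40 to -1.91), MCCC2 in 12 (1.26 to 1.68), S100P in 11 (1.99 to 2.88), and AGR2 (0.86 to 2.22), DBI (1.11 to 1.62) and DDC (-0.90 to -0.72) in 6 each. Values that never passed changed sign in up to 35 of 308 cases with the values as deposited, and in 108 of 309 with the order as deposited, which sets unrelated probe sets side by side. Apart from fewer arrays or probe sets, the cause of these changes was not tested. Whether the 3 arrays per group or signal over background limits precision more was not tested.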

Other observations

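The shares over all splits of the samples were planned before the results. The parting of the labellings of the F test by whether a control moves was not in that plan, and the levels by array were looked up only after the results were seen.

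Androgen-repressed genes were low on every array of experiment 2: their mean stood at -0.59 in its control, against 0.19 and 0.41 in the controls of experiments 1 and 3. With DHT it was -0.82 in experiment 2 against -0.47 and 0.07, and with DHEA -0.74 against -0.19 and -0.07. This level thus marks the whole experiment and not its control alone. LDHA, a glycolytic enzyme, stood at 13.09 in that control against 11.27 and 11.57, and S100P at 10.31 against 7.73 and 8.54. Both were also highest in experiment 2 among the treated arrays of a group. LDHA was 13.08 with DHT (12.46 and 12.26 in experiments 1 and 3) and 13.22 with DHEA (11.64 and 12.39). S100P was 12.03 with DHT (11.18 and 10.85) and 10.66 with DHEA (9.77 and 9.15). On the androgen-induced list all 3 DHT arrays stood at a like level (0.34, 0.38 and 0.38), whatever the level of their control, and the DHEA arrays at 0.23, 0.41 and 0.64. With the control of experiment 2 left out, 475 probe sets passed with DHT and 284 with DHEA.

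Other splits of the 6 arrays of a comparison, 10 in all and 4 of them parting every pair, show how often as many calls arise. With DHT 1 of 10, the true one, called 7 or more probe sets (highest other 0), and with DHEA 1 of 10 called 1 or more (highest other 0). Between the steroids the true split called 0, so all 10 call as many by construction and the share says nothing (highest other 2, and 0 among those parting every pair). For the gene lists, as many as the true groups were called by 1 of 10 with DHT (10 lists, highest other 9), 3 of 10 with DHEA (9, highest other 13) and 6 of 10 between the steroids (3, highest other 9). Among splits parting every pair the highest others are 9, 11 and 7. With 10 splits no share under 0.05 can be reached. For the F test 4 of 36 labellings within experiments called as many as the true one (1 probe set), itself among them. This share is not under the 0.05 set beforehand, so by that rule chance is not excluded. The other 3 of these 4 only exchange DHT and DHEA and keep every control, so they could not lose a probe set that rises with either steroid. None of the 32 labellings that move a control called any, but this count was not planned.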
